A study of Mus musculus with 5 samples.

How the data were processed

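RNA of murine lung, by the labels' source name, was measured on 5 Affymetrix mouse expression arrays, 2 of A/J mice given saline into the trachea and 3 of A/J mice given IL-13 (interleukin-13, a T helper 2 cytokine) by the same route. The array titles carry the numbers 6 and 48 for saline and 6, 18 and 48 for IL-13. They could be time points, but the labels give no unit, so they are called title numbers. Each array is named by its treatment and its number. Each combination of treatment and title number holds 1 array. Nothing in the labels says how many animals an array stands for or whether the arrays come from separate animals, so p-values measure only the spread between these arrays, which also differ in title number within a treatment.

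The values are those the authors deposited in one table of 12488 probe sets, read as intensity on a linear scale. The software, the background correction and the scaling target are not given in the sources used here. The deposited values themselves show that each array was scaled: their 2% trimmed mean lies between 800.39 and 800.47 on all 5 arrays. Detection calls were not analysed here.

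Control probe sets of the manufacturer (66) were left out, which leaves 12422. A probe set is a group of short oligonucleotides for one transcript. The platform annotation gave exactly 1 gene symbol for 10833 of these probe sets, several for 396 and none for 1193, and no gene was named from a probe set with several. Symbols were updated through the gene number to those of the RefSeq gene table for 10817 probe sets. The endings _f_at, _s_at, _r_at, _g_at and _i_at mark probe sets whose probes may be shared by related transcripts or were chosen under relaxed rules. No coordinates are given, because the files name no genome build.

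Arrays were scaled to a common 2% trimmed mean, values below the pooled 20th percentile (55.3) were set to it, and log2 was taken. Probe sets above the pooled 40th percentile (210) on at least 2 of the 5 arrays were tested, 7811 in all, representing 5983 genes. The comparison of IL-13 with saline used lmFit and eBayes of limma 3.58.1 in R 4.3.3 with treatment as the only term (3 residual degrees of freedom, 3.46 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is the moderated standard error of the log2 difference. A matched pair of 1 array against 1 has no test. For such pairs a count was made of probe sets at least 2-fold apart whose higher value was above the pooled median (343). A fold in which the lower array lies below 55.3 is a lower bound and is written with "at least". Where a gene has several probe sets, every one was tested, the one with the highest mean log2 value stands for the gene in gene lists, and disagreement is stated for named genes.

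Of 26 gene lists of processes and cell types, 25 had the minimum of 4 measured genes. The list of eosinophil genes had none of its 11 genes among the probe sets tested. Lists were tested with camera (preset correlation 0.01, and again with the correlation estimated per list) and with fry, both of limma, with Benjamini-Hochberg adjustment over the lists. For pairs of arrays the median of a list was ranked among 10000 random lists of the same size matched on mean expression in 10 bins. That percentile describes these arrays and is not a test.

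The groups, the tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the 12 largest increases and 12 largest decreases past the threshold. Where fewer passed, it was filled with genes whose 3 IL-13 arrays lay beyond both saline arrays and that differed at least 2-fold the same way in both matched pairs, said not to have passed. It also named the 8 largest increases and decreases of each matched pair, the 5 genes with the largest excess of each IL-13 array over the next highest array, up to 4 members of each list, and any member of the lists of goblet cell and mucus genes and of IL-4 and IL-13 response genes. Further lists (salivary gland, heart atrium, immature thymocyte, T cell receptor complex, lymph node, thyroid and parathyroid, cartilage, alveolar type II and squamous epithelium) were written after the data had been seen and are used only in the closing section.

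Alternatives were quantile normalization, the values as deposited, a common median of bright probe sets, floors at the 10th and 40th percentile, no filter and a filter at the 60th percentile (534), limma with trend and robust settings, title number as a block over the 4 arrays of 6 and 48, leaving out each array in turn, fold thresholds of 1.5 and 3, and, added after the data were seen, the other saline array as the control of each pair. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.

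Simulated data took the real means and moderated standard deviations of the 7811 probe sets, with independent noise and no shared array effect. The limma fit was tested on them with 200 probe sets changed, so the shares recovered hold for such noise only. It recovered 58% of 50 changes of 1 on the log2 scale, 98% of 50 changes of 2, 96% of 50 changes of 3 and 100% of 50 changes of 4, with 11 unchanged probe sets among 187 calls. camera called a list of 15 genes shifted by 1 and none of 20 unshifted lists. The simulated genes were uncorrelated, so this does not test camera on correlated lists such as the T cell list (estimated correlation 0.44). With random lists matched on expression, the shifted list had percentile 100 and 1 of the 20 unshifted lists lay outside the central 95%. In 1 simulated array against 1, 91 of 91 large changes and 137 unchanged probe sets reached 2-fold. Between the real saline arrays, 203 of all 12422 probe sets were at least 2-fold higher and 204 lower.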

Results

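The data are intensities of 12422 probe sets on 5 arrays of RNA labelled as lung, from A/J mice, 2 after saline (title numbers 6 and 48) and 3 after IL-13 (title numbers 6, 18 and 48). IL-13 is a cytokine of T helper 2 cells that acts on airway epithelium. The series is about goblet cells, the mucus-secreting cells of the airway surface, and the arrays address which transcripts differ in level after IL-13 was put into the trachea. The median intensity lay between 322.6 (saline 6) and 356.9 (IL-13 18), and 59% to 61.1% of the probe sets exceeded 210 on each array. Across tested probe sets, which are not independent replicates, Pearson's r of log2 values between arrays lay between 0.913 and 0.956. The array saline 6 had the lowest values with the others, 0.913 to 0.923. There were no replicates of any single combination of treatment and title number.

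Over all 5 arrays, 3 named genes were lower after IL-13 and passed the limma test, each with an adjusted p of 0.0398 and with all 3 IL-13 arrays below both saline arrays. Inpp5d, a phosphoinositide phosphatase of blood cells, differed by -2.37 on the log2 scale (SE 0.19). IL-13 6 (35.38) and IL-13 18 (55.27) lay below the floor of 55.3 and were set to it, so the difference depends on the floor (-2.58 with the 10th and -0.49 with the 40th percentile) and the SE leaves out the spread below it. Its second probe set 161678_at did not show this: it read 420.1 and 166.3 with saline and 291.3, 262.8 and 116.1 with IL-13. Sh2d2a, a T cell adapter protein, differed by -2.32 (SE 0.21), from 819.2 and 600.5 with saline to 134.9, 159.9 and 127.6 with IL-13. Mast3, a protein kinase, differed by -2.23 (SE 0.18). With the floor at the 40th percentile the difference was -1.74 for Sh2d2a and -0.9 for Mast3. With title number as a block it was -2.42 for Sh2d2a and -2.19 for Mast3. The only probe set that passed as higher, 162484_r_at, has no gene listed and differed by 2.09 (SE 0.19), with saline 6 (50.61) set to the floor and saline 48 (63.7) near it. In all, 1 probe set was higher and 3 were lower of 7811 tested, while 413 and 310 had an unadjusted p under 0.05. All 3 IL-13 arrays lay above both saline arrays for 14.8% of the tested probe sets and below both for 11%, where chance gives 10% in each direction. Both arrays of title number 6 lay above or below the other 3 for 27.1% of tested genes, with 1 probe set per gene. An excess over chance is therefore not particular to the split by treatment. All 4 calls were lost with title number as a block (lowest adjusted p of any probe set 0.11), with a floor at the 10th (0.0656) or 40th percentile (0.185), with no filter (0.0962) and with trend and robust settings (0.186). None of the 4 was kept when saline 6 or any one IL-13 array was left out, and leaving out saline 48 gave 3 higher and 10 lower.

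The largest differences that did not pass the test, but held at least 2-fold in both matched pairs with no overlap of arrays, were in Clca1 and Chil3. Clca1, a secreted protein of goblet cells, read 3117 and 284.7 on saline 6 and saline 48 and 21500, 29080 and 22010 on the IL-13 arrays in order of title number, a log2 difference of 4.67 (SE 0.90, adjusted p 0.261). That was 6.9-fold at 6 and 77.3-fold at 48, and leaving out 1 array gave log2 differences from 2.94 to 6.4. Clca1 was the brightest probe set on IL-13 18 and close to the highest value on IL-13 48 (23414), and saturation, which would make these folds too small, was not tested. These values are from 162287_r_at, whose ending marks probes that may be shared or were chosen under relaxed rules. A second probe set of Clca1, 100623_at, has no such ending. It was dim on every array, from 24.57 to 156.8, and did not show this difference. Chil3, a chitinase-like protein of macrophages, read 387.8 and 92 with saline and 2566, 7595 and 3182 with IL-13 (log2 difference 4.39, SE 0.69, adjusted p 0.187), from 3.35 to 5.43 leaving out 1 array. Fcgbp, a mucus protein that binds immunoglobulin, differed by 1.88 (SE 0.30, adjusted p 0.187) on one probe set and by 1.83 (SE 0.26, adjusted p 0.183) on the other. Tm7sf2, a sterol reductase, differed by 1.54. The hormone gene Sct differed by 1.53 (f_at probe set), the aldehyde dehydrogenase gene Aldh1a7 by 1.53 and the endothelial adhesion gene Pecam1 by 1.44, with adjusted p from 0.183 to 0.312. The decreases of this kind included genes of the T cell receptor complex. Septin1 differed by -2.54 (IL-13 6 below the floor), Cd3e by -2.47, the kinase gene Pik3cd by -2.33, Cd8b1 by -2.29, the recombinase gene Rag1 by -2.08, the chromatin organiser gene Satb1 by -2.03, Cd3g by -2.02, Cd3d by -1.95 and the growth factor gene Tgfb1 by -1.77, with adjusted p from 0.183 to 0.469. Of the Rag1 probe sets, 161740_r_at did not show this (531.9 and 756.3 with saline, 742.5, 898.9 and 679.7 with IL-13). Leaving out 1 array gave -3.13 to -1.65 for Cd3e and -2.8 to -1.58 for Cd8b1. For Rag1 (93683_at) it gave -2.75 to -1.55 and for Satb1 -2.52 to -1.53.

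Genes of goblet cells and mucus were higher after IL-13 as a list. Of 15 measured members, 12 had a higher mean and 3 a lower one, the median log2 difference was 0.46, and camera gave an adjusted p of 9.13e-05. With an estimated correlation the adjusted p was 0.472, and with fry it was 0.242. None of its members passed over all probe sets tested, and 5 did when adjusted over the list alone, all of them higher. Beside Clca1 and Fcgbp, Agr2 (an f_at probe set), a protein of the endoplasmic reticulum of mucus cells, differed by 1.39 (SE 0.35). The lectin gene Itln1 differed by 1.16 (SE 0.27) and the trefoil peptide gene Tff1 by 0.86 (SE 0.26). Muc1, a membrane mucin, differed by 0.46 (SE 0.25). Spdef, a transcription factor of goblet cells, was at least 7.73-fold higher at 6 and read 0.945 times the saline value at 48, but the saline arrays themselves read 38.42 and 242.3. The probe set of the mucin gene Muc5ac was below 55.3 on all 5 arrays, so it gave no fold. The median of the list lay at percentile 100 of random lists in both matched pairs, at log2 differences of 0.49 and 0.44. That median also differed by -0.22 between saline 48 and saline 6, at percentile 4.92.

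Genes of the IL-4 and IL-13 response did not pass as a list (28 measured, 17 higher and 11 lower, median 0.22, camera adjusted p 0.226). None passed over all probe sets tested, and 2 passed when adjusted over the list alone. Chil3 and Postn, a matrix protein (0.85, SE 0.17), were those 2. The median of the list was 0.52 at 6 and -0.14 at 48. Members differed in which pair stood further above saline. Chil3 was 6.62-fold higher at 6 and 34.6-fold at 48, but this order comes from the saline arrays (387.8 and 92), and it turned with the other saline array as control. Others had the larger fold at 6: the eosinophil chemokine Ccl11 was 6.63-fold higher at 6 and 1.56-fold at 48, the lipoxygenase gene Alox15 4.01-fold and 1.62-fold, and the chemokine Ccl17 at least 4.88-fold at 6 (saline 6 44.93, saline 48 161.5) and 0.525 times the saline value at 48. Serpinb2, a protease inhibitor, was 6.0-fold higher at 6 and read 0.849 times the saline value at 48. Arginase, Arg1, was 4.1-fold higher at 6 and 0.597 times the saline value at 48. The chitinase gene Chia1 read 20430 on saline 6, 185.6 on saline 48, 305.4 on IL-13 6, 2619 on IL-13 18 and 276.3 on IL-13 48. The suppressor of cytokine signalling Socs1 differed by -0.68 (SE 0.20). The difference between the pairs was not tested.

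**Figure D1:**
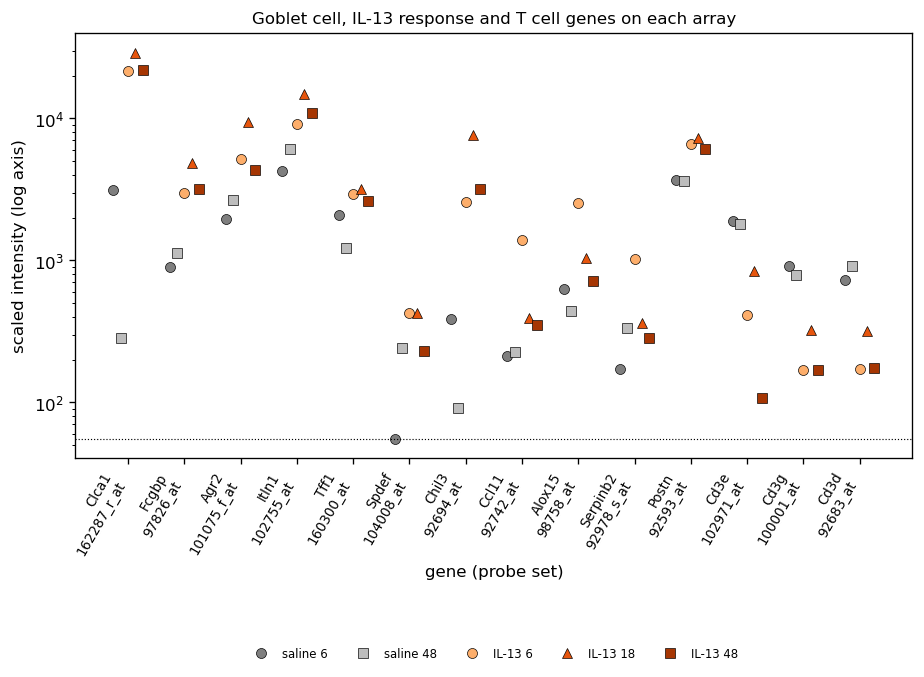
Scaled intensity (log axis) of 14 genes on each of the 5 arrays, 1 point per array, with grey symbols for saline and orange symbols for IL-13; the dotted line is the floor of 55.3, and lower values are drawn on it. The 3 IL-13 points of Clca1, at 21500, 29080 and 22010, lie above both saline points, and those of Cd3e, Cd3g and Cd3d lie below them.

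T cell genes were lower after IL-13, by the list of T cell and natural killer cell genes, whose natural killer cell markers were not among the probe sets tested. All 15 measured members had a lower mean, 12 with no overlap of arrays, and the median log2 difference was -1.30 (camera adjusted p 1.5e-14). With an estimated correlation the adjusted p was 0.472, and with fry it was 0.304. None passed over all probe sets tested, and 7 passed when adjusted over the list alone. Cd3e, a chain of the T cell receptor complex, was 4.6-fold lower at 6 and 16.7-fold lower at 48. The median was -1.48 at 6, -1.63 at 48 and -0.70 for IL-13 18 against the mean of both saline arrays. The list of thymus and adipose tissue genes moved the same way (15 measured, 13 lower, median -0.72, camera adjusted p 1.89e-05). With an estimated correlation its adjusted p was 0.472, and with fry 0.304. It shares Cd8b1 with the T cell list, and its other large differences were in Ccr9 (-1.40), the lipid droplet gene Cidec (-1.19) and Dntt (-1.17), a polymerase of immature lymphocytes. The median of the thymus and adipose list was -1.17 at 6 and -0.31 at 48, and -1.08 to -0.26 leaving out 1 array. That median also differed by -0.64 between saline 48 and saline 6.

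Among lists of structural and growth genes, 4 more were higher by camera. Extracellular matrix genes had a median of 0.30 (31 of 36 higher, adjusted p 0.000393) and included Postn, the collagen chaperone Serpinh1 (0.76) and Col3a1 (0.63), while Tgfb1 was lower. The estimated correlation gave an adjusted p of 0.521 and fry 0.304. Cell cycle genes had a median of 0.23 (27 of 34 higher, adjusted p 0.00279), with Aurkb at 1.66, Cdk1 at 0.83, Mcm4 at 0.55 and Cdc20 at 0.53, and an adjusted p of 0.472 with an estimated correlation and 0.304 with fry. Their median was -0.24 between saline 48 and saline 6, at percentile 0.1. Smooth muscle and fibroblast genes had a median of 0.28 (19 of 22 higher, adjusted p 0.00625), with Tcf21 at 0.94, Mfap4 at 0.77 and Mfap2 at 0.56, and an adjusted p of 0.550 with an estimated correlation and 0.308 with fry. Alveolar epithelium genes had a median of 0.64 (11 of 14 higher, adjusted p 0.0195). With an estimated correlation the adjusted p was 0.550, and with fry it was 0.401. In that list Hopx differed by 1.11, Slc34a2 by 1.09 (-0.17 at 6 and -0.39 at 48), Emp2 by 0.95 and Igfbp2 by 0.83. The list's median was 1.06 for IL-13 18 and 0.14 and 0.19 in the pairs at 6 and 48, and without IL-13 18 the camera adjusted p was 0.378.

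The other lists did not pass camera, and no list passed fry (lowest adjusted p 0.242). Club cell genes, of the secretory cells that line small airways, had a median of 0.06 (9 measured, adjusted p 0.233), with Aldh1a7 at 1.53 and Cyp2s1 at 0.46. Ciliated cell genes had a median of 0.21 (9 measured, adjusted p 0.140), with Kif9 at 1.35 and Tekt1 at 0.46. Macrophage and dendritic cell genes had a median of -0.22 (27 measured, adjusted p 0.0978), with Mpeg1 at -1.19 and H2-Aa at -0.84. Neutrophil genes had a median of 0.09 (8 measured, adjusted p 0.226), with Csf3r at 1.04 and Il1r2 at 0.77. B and plasma cell genes had a median of -0.42 (12 measured, adjusted p 0.233) that was -1.15 at 6 and 0.58 at 48, with Cd79a at -1.04 and Ly6d at 0.89. Mast cell and basophil genes had a median of 0.27 (5 measured, adjusted p 0.226), with Kit at 0.74 and Hdc at 0.48. Erythroid cell and platelet genes had a median of 0.18 (6 measured, adjusted p 0.212), with Gata1 at 0.91 and Car2 at 0.42. Endothelial genes had a median of -0.03 although camera pointed up (20 measured, adjusted p 0.959), with Pecam1 at 1.44 and Thbd at 0.68. Heart and skeletal muscle genes had a median of -0.05 (33 measured, adjusted p 0.686), with Myh6 at -1.25 and Myl7 at -0.92, both bright on saline 6 (3986 and 7547) and not on saline 48 (133.2 and 129.9). The differences of Cd79a, Tekt1, Myh6 and Myl7 changed sign when 1 array was left out. That of Kif9 then ranged from 0.52 to 2.18 and that of Hdc from 0.05 to 0.9.

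Of the process lists that did not pass, chemokines had a median of -0.08, a mean of 0.13 and a camera direction that pointed up (14 measured, adjusted p 0.771), with Ccl5 at -1.78 (-3.36 to -0.20 leaving out 1 array, and 1.68-fold higher in the pair at 48) and Ccl11 at 1.41. Acute phase genes had a median of -0.02 (20 measured, adjusted p 0.220), with Vcam1 at -1.25 and Saa2 at -0.95. Arginine and polyamine genes had a median of 0.18 (12 measured, adjusted p 0.771), with Sat1 at -0.64 and Arg1 at 0.42. Interferon response genes had a median of -0.13 (22 measured, adjusted p 0.210), with Psmb8 at -0.74 and Irf7 at 0.73. Genes of the endoplasmic reticulum and secretory pathway had a median of 0.13 (28 measured, adjusted p 0.212), with Dnajc3 at 0.85 and Trib3 at -0.85. Xenobiotic and oxidative metabolism genes had a median of 0.02 and a camera direction that pointed down (33 measured, adjusted p 0.686), with Cyp2e1 at -0.96. Immediate early and stress genes had a median of 0.15 (30 measured, adjusted p 0.226), with Fkbp5 at -1.04 and Atf3 at 0.90. Circadian clock genes had a median of -0.16 (14 measured, adjusted p 0.249), with Per1 at -0.66 and Dbp at -0.59. The differences of Arg1 and Dbp changed sign when 1 array was left out, and that of Per1 ranged from -1.24 to -0.07.

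**Figure D2:**
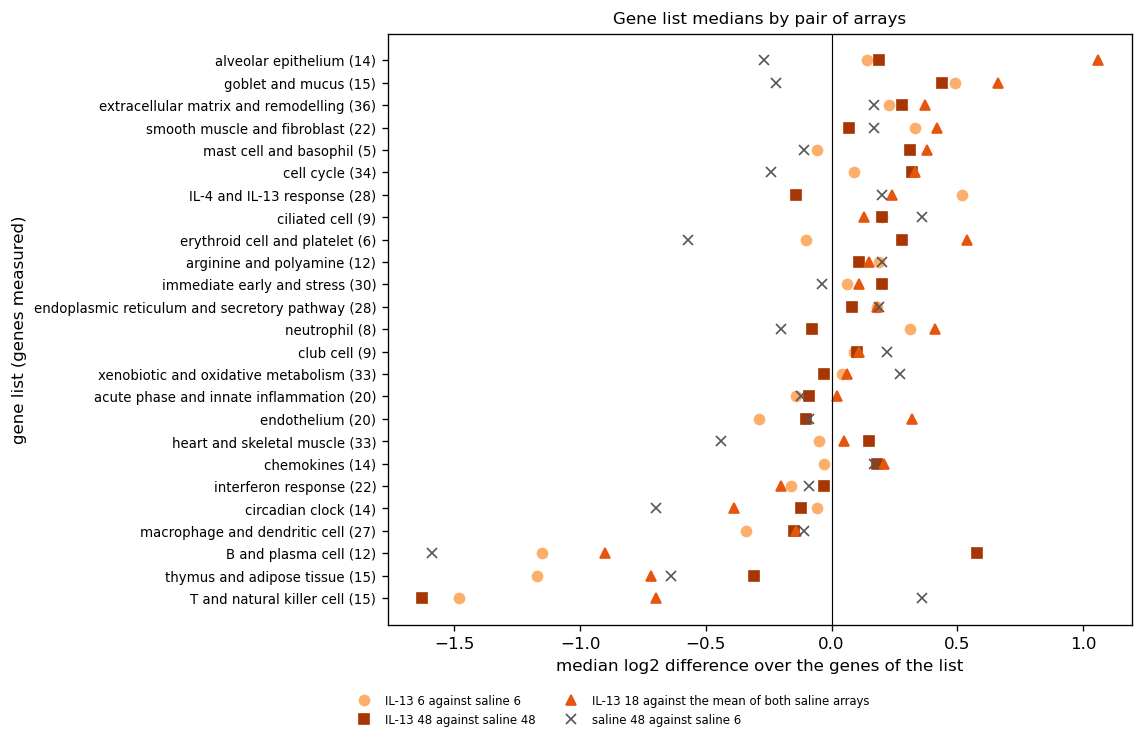
Median log2 difference of each of 25 gene lists (number of measured genes in brackets) for IL-13 6 against saline 6, IL-13 48 against saline 48, IL-13 18 against the mean of both saline arrays, and saline 48 against saline 6; 1 point per pair. The T cell list lies at -1.48 and -1.63 in the matched pairs, and the goblet cell list at 0.49 and 0.44.

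In the pair at title number 6, 229 probe sets were at least 2-fold higher and 266 at least 2-fold lower on IL-13 6 than on saline 6. The largest increases were in the small proline-rich gene Sprr2b (8.21-fold) and the related pseudogene Sprr2c-ps (33.9-fold). Both are f_at probe sets that may take up related transcripts. The rest of the 8 largest were in Spdef (at least 7.73-fold), the calcium sensor gene Vsnl1 (7.21-fold), Clca1 (6.9-fold), Ccl11 (6.63-fold), Chil3 (6.62-fold) and the phosphodiesterase gene Gpcpd1 (6.54-fold). The largest decreases were in transcripts of salivary glands that were much brighter on saline 6 than on any other array. These were Smr3a (at least 416-fold), Dnase1 (at least 263-fold), Car6 (at least 257-fold) and Pip (at least 193-fold). Bpifa2 (109-fold), Amy1 (69-fold) and Klk1b5 (at least 59.7-fold) followed, and Chia1 was 66.9-fold lower. Smr3a read 22980 on saline 6 and at most 28.65 on the other 4 arrays. Against saline 48 in place of saline 6, a comparison chosen after the data were seen, the counts were 127 higher and 148 lower, and the log2 difference at 6 became 0.82 for Spdef, 0.79 for Gpcpd1 and 1.14 for Vsnl1.

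In the pair at title number 48, 74 probe sets were at least 2-fold higher and 136 at least 2-fold lower on IL-13 48 than on saline 48. Clca1 (77.3-fold) and Chil3 (34.6-fold) were followed by the muscle creatine kinase gene Ckm (at least 7.9-fold), the lymph node endothelial gene Glycam1 (7.23-fold), the immunoglobulin segment Ighv14-2 (at least 7.14-fold), Gsx1 (6.61-fold), Ift46 (5.88-fold) and Tmem129 (4.42-fold). Decreases were led by Cd3e (16.7-fold), Cd8b1 (15.8-fold), Rag1 (11.1-fold), Znrf1 (10.9-fold), Satb1 (8.39-fold), Cd2 (at least 8.28-fold), Cd27 (at least 6.34-fold) and Pik3cd (6.27-fold), of which Cd3e, Cd8b1, Cd2 and Cd27 encode T cell surface proteins. Against saline 6 the counts were 269 higher and 294 lower, Glycam1, Ighv14-2 and Ift46 were then lower with IL-13, and the log2 difference at 48 became -0.59 for Cd27, 1.21 for Ckm, 2.82 for Clca1 and 3.04 for Chil3.

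In both matched pairs, 9 probe sets were at least 2-fold higher and 51 at least 2-fold lower, of 6220 that were bright enough in each. Of those 6220, 194 were higher and 205 lower at 6 and 52 were higher and 103 lower at 48, and independent lists of these sizes would share 1.62 and 3.39. The 2 pairs share no array. Another 20 probe sets moved at least 2-fold in opposite directions, more than the 9 that were higher in both. Independent lists leave out that some genes vary more between arrays whatever the treatment. An excess over them is therefore not by itself a sign of an effect of IL-13. As a measure of how far control arrays lie apart, saline 48 was at least 2-fold higher than saline 6 for 203 probe sets and lower for 204, which is more than in the pair at 48.

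Across the IL-13 arrays, the largest excess of IL-13 6 over the next highest array was in Sprr2c-ps (19.6-fold). The keratin gene Krt6a was 3.85-fold, Ccl11 3.55-fold, Dnajc11 3.05-fold and Serpinb2 2.85-fold above it. The largest excesses at 18 were in the following 5 genes: Slc34a2, a phosphate transporter of alveolar cells, was 10.8-fold, the surfactant gene Sftpb 9.12-fold, Chil1 8.71-fold, the surfactant gene Sftpc 6.57-fold and the metalloelastase gene Mmp12 5.88-fold above the next highest array. At 48 the excess was smaller, with Gsx1 at 3.18-fold, the immediate early gene Fos at 2.62-fold, Tmem129 at 2.6-fold, the interferon-induced gene Iigp1 at 2.34-fold and Sprr1b at 2.3-fold. A second Sprr1b probe set, 100446_r_at, was bright on every array and not highest at 48 (11310). IL-13 18 has no saline array of its number; against the mean of both, 124 probe sets were at least 2-fold higher and 127 lower.

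**Figure D3:**
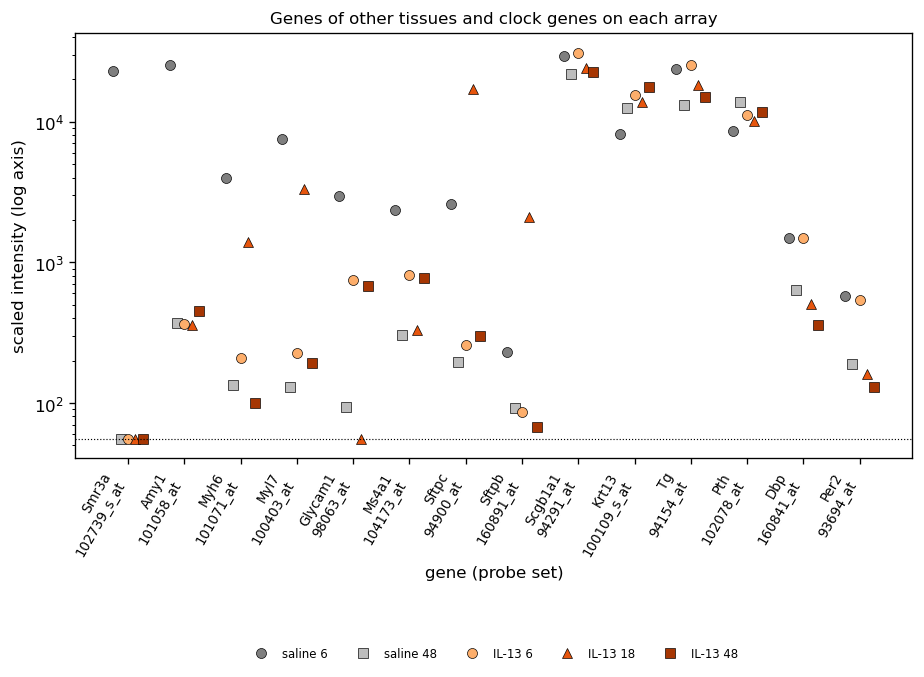
Scaled intensity (log axis) of 14 genes of other tissues, surfactant genes and clock genes on each of the 5 arrays, 1 point per array, with the floor of 55.3 as a dotted line and lower values drawn on it. Smr3a is at 22980 on saline 6 and at the floor on the other arrays, and Sftpc is at 17180 on IL-13 18.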

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

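All tests in this part were chosen after the results they concern had been seen. Named genes that lay at least 2-fold apart in opposite directions in the pairs at 6 and 48, with the higher value above the pooled median (343) in each pair, were picked out, and the difference between the pairs was not tested, since each pair is 1 array against 1. The difference of the pairs (log2 at 48 minus log2 at 6) was 5.28 for Ighv14-2, 4.84 for Glycam1, 4.24 for Ift46, 3.51 for Cd79a and 3.45 for Tmem129. Glycam1 read 2959 on saline 6, 93.66 on saline 48, 746.9 on IL-13 6, 35.76 on IL-13 18 and 677.3 on IL-13 48, and Cd79a, a B cell receptor chain, read 2126, 277.5, 527.7, 127.1 and 782.9 on the same arrays.

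T cell genes were lower on the IL-13 arrays. A common factor on all probe sets is argued against as the cause. The median log2 difference of all tested probe sets was only 0.019 to 0.04 under each scaling. The T cell list stayed at -1.32 or lower under quantile normalization and a common median. Rescaling by so little could not have moved it far, so this is no separate evidence. Less lymph node tissue is argued against as the cause in the pair at 48, because 8 genes of B cells and lymph node vessels had a median of 1.42 there, where T cell receptor genes had -1.63. The list of B and plasma cell genes, fixed beforehand, had 0.58 there. It stays open for the other arrays, since the medians of the same 8 genes were -1.86 in the pair at 6 and -1.33 for IL-13 18, beside -1.48 and -0.99 for T cell receptor genes. A smaller amount of thymus tissue in the IL-13 samples stays open: 8 genes of immature thymocytes had a median difference of -1.28, against -1.30 for 11 T cell receptor genes, but the thymocyte genes were listed after several of them had been seen to be lower, so this does not support it, and on IL-13 18 the medians were -0.28 and -0.99. Mature T cells also express some of the thymocyte genes, among them Cd8a and Cd8b1, so the list is not particular to the thymus. Rag1 entered with the probe set of the higher mean log2 value, which did not differ that way, while its other probe set did. An effect of IL-13 on T cells in the lung was not tested and stays open.

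Salivary gland genes stood out on saline 6. Of 12 such genes on the array, 91.7% were at least 2-fold above every other array (Egf was not), with a median intensity of 11100 against 150 to 220 elsewhere. These include 7 genes already named as the largest decreases in the pair at 6, so the share restates that result, and salivary gland tissue in that sample stays open. An effect of title number 6 in both treatments is argued against, because the same genes were not raised as a set on IL-13 6. Their median difference from the mean of the arrays of title number 48 was 0.00. This 0.00 comes from Smr3a, Dnase1, Car6 and Pip, which lay below the floor on all of these arrays. Amy1, above it, read 364.6 on IL-13 6 against 369.8 and 447.6, but Prpmp5 read 892.8 against 374.2 and 595.3. An effect of title number 6 after saline alone was not tested. Saline 6 also held the highest medians for heart atrium genes (3250, with 1680 on IL-13 18 and 214 to 309 on the others) and for lymph node genes (1470, with 74.7 to 401 on the others). Because saline 6 is the only control at 6, decreases in that pair are open to this.

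Clca1 and Chil3 were higher on saline 6 than on saline 48, 11-fold and 4.22-fold. RNA of an IL-13 sample in saline 6 cannot be told apart from a true difference: Clca1 held 11.8% and Chil3 6.79% of the mean IL-13 level on saline 6 above saline 48, and 2 other genes at least 4-fold above saline 48 on all IL-13 arrays held a median of 128%, too few genes and picked by a low value on saline 48. Other goblet cell genes that passed over their list alone were divided. Fcgbp (97826_at) read 895 on saline 6 against 1135 on saline 48, Agr2 1944 against 2646 and Itln1 4294 against 6078. Tff1 read higher on saline 6, 2087 against 1220. Their differences with IL-13 were smaller than that of Clca1, so these values do not decide it. A difference between title numbers after saline was not tested.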

How the results depend on the processing

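The other saline array as a control was chosen after the data were seen; all other settings were fixed before. Over all 5 arrays (1 higher, 3 lower) the counts were 0 and 3 with quantile normalization, 0 and 1 with the 60th percentile filter, and 0 and 0 with a floor at the 10th or 40th percentile, no filter, trend and robust, or title number as a block. Leaving out 1 array gave 0 to 3 higher and 0 to 10 lower; without saline 48, 13 probe sets passed, of which 3 were among the 4. A lone saline array was assumed to vary like the IL-13 arrays. The unadjusted counts lay between 460 and 1276. Why the calls ended was not tested, except that fewer arrays leave fewer degrees of freedom. Deviations of arrays with the same title number from their treatment means correlated at 0.097 for 6 and 0.133 for 48. The deviations of the saline arrays mirror each other, so IL-13 6 with saline 48 gave -0.097. This check therefore cannot decide whether title number pairs the arrays. Treatment was the only term of the main fit, which was fixed before the data were examined. In the circadian clock list, 12 of 14 genes separated the arrays of title number 6 from the others, so a shared effect of title number stays open.

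With no requirement on the higher value the pair at 6 had 585 higher and 478 lower, the pair at 48 297 and 288, both pairs 38 and 85, and the saline arrays 436 and 423. The stricter requirement gave 45 and 82 at 48. With a 1.5-fold threshold the counts were 784 and 629 at 6, 346 and 362 at 48, 72 and 118 in both, and 786 and 586 between saline arrays; with 3-fold they were 66 and 103, 22 and 53, 2 and 16, and 48 and 90. With the other saline array they were 127 and 148 at 6 and 269 and 294 at 48, and Chia1 at 6 became 0.72, Glycam1 at 48 -2.13, Ighv14-2 -1.28 and Ift46 -0.76. List medians that changed sign with it included 0.04 for macrophage, 0.83 for B cell and -0.23 for club cell genes at 6, and 0.03 for IL-4 and IL-13 response, -1.1 for B cell, -0.07 for alveolar and -0.18 for heart and skeletal muscle genes at 48. Those of the arginine, xenobiotic, clock, heart and skeletal muscle and erythroid lists also changed sign in at least one pair, by less than their medians differed between the saline arrays.

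Of the lists, 5 were higher and 2 lower by camera; an estimated correlation left 0 and 0, the block gave 3 higher and 3 lower, and leaving out 1 array gave 3 to 7 higher and 2 to 5 lower. The T cell and goblet cell lists kept their call in all other settings. Calls were lost for cell cycle with the 60th percentile filter (adjusted p 0.0797), for alveolar epithelium with no filter (0.0515) and the block (0.427) and for smooth muscle with the block (0.0734). They were gained for macrophage genes, as lower, with that filter (0.0166) and the block (0.0274), and for endoplasmic reticulum genes, as higher, with that filter (0.0317). Leaving out 1 array also ended the calls of the cell cycle, alveolar and smooth muscle lists and gave calls to lists that had not passed. The direction that camera gives, which can differ from the sign of the median, turned for lists that had not passed, given here with their medians: chemokines (median -0.16 with quantile normalization, -0.1 with the mean of all probe sets, -0.06 to 0.16 leaving out 1 array), heart and skeletal muscle (-0.03 with quantile normalization, -0.19 to 0.23 leaving out 1), endothelium (-0.02 with no filter, -0.04 with the stricter filter, -0.17 with the block, -0.17 to 0.13 leaving out 1), xenobiotic metabolism (-0.11 to 0.15), circadian clock (-0.53 to -0.01), B cell (-1.36 to 0.54) and erythroid genes (-0.11 to 0.45). Among named genes the log2 difference turned for Slc34a2 (-0.28 with the block; -0.28 to 2.02 leaving out 1), and leaving out 1 array for Chia1 (-5.08 to 1.70), Arg1 (-0.23 to 0.85), Dbp (-1.20 to 0.02), Cd79a (-2.51 to 0.43), Tekt1 (-0.27 to 1.20), Myh6 (-3.70 to 1.21) and Myl7 (-3.85 to 2.01). The cause was not tested. Of values of named genes under an alternative, 1239 stayed on their side of the threshold or within the spread of the saline arrays, 55 moved further, 27 lost and 2 gained a call, and 13 turned. Only 3 named genes had passed, so lost calls come from those alone. For the other tested genes, staying on their side says nothing of the size of the difference. Values near the floor of 55.3 limit what dim genes such as Muc5ac can show.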

Other observations

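All tests in this part, and the lists they use except that of clock genes, were chosen after the data had been seen. Of 12 genes of squamous epithelium, 5 had their highest value on IL-13 6: Krt4, Krt6a, Sprr1a, Sprr2b and Scel. Krt4 read 15200 to 20690 and Krt13 8144 to 17700 over the 5 arrays. Krt6a (104369_at), a keratin of wounded epithelium, read 2284 and 3413 with saline and 13140, 4167 and 4889 with IL-13 at 6, 18 and 48. Sprr1a read 796.1 and 1351 with saline and 3801, 1764 and 1520 with IL-13, and Sprr2b 2390 and 2248 with saline and 19620, 11480 and 4234 with IL-13. Scel, a protein of the cornified envelope, read 202.6 and 616.6 with saline and 1028, 811.2 and 979.7 with IL-13. Other members were dim: Krt5 and Krt14 were below the floor of 55.3 on 3 arrays each, and Ivl read 10.47 to 39.08. The club cell protein gene Scgb1a1 was at percentile 100 on all 5 arrays.

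Of 8 heart atrium genes, 7 were higher on saline 6 and IL-13 18 than on the other 3 arrays. The other, Actc1 (an f_at probe set), read 9837 to 16250 on all arrays. Myl7 read 7547 on saline 6 and 3323 on IL-13 18, against 129.9 to 224.8 on the others, and Nppa 2650 and 2033 against 415.8 to 537.2.

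A thyroid and a parathyroid transcript were among the brightest on all arrays, although the labels name lung as the source. Tg (thyroglobulin) read 13170 to 25520 and Pth (parathyroid hormone) 8658 to 13790, and the lowest percentile of either on any array was 98.0. The other thyroid genes listed were less bright: Pax8 read 607.8 to 1494, Dio1 365.4 to 1858 and Tshr 41.09 to 378.9. Of the cartilage genes Acan read 948.4 to 3278 and Col9a1, Col9a2, Col9a3 and Col11a1 406.6 to 1130, but Matn1 read 82.9 to 326.9, Col2a1 only 86.42 to 144.5, Matn3 41.53 to 150.4 and Hapln1 37.98 to 108.3. The surfactant gene Sftpc, abundant in alveolar tissue, was at percentile 99.8 on IL-13 18 and 91.2 on saline 6 but at 39.2 to 46.7 on the other 3. The surfactant gene Sftpb was at percentile 88.4 on IL-13 18 and at 22.3 to 42.9 on the others. Napsa, also expressed in alveolar cells, read 1805 to 2837 on all arrays and was not higher on IL-13 18 (2005). Skeletal muscle transcripts were also bright on all arrays: Tnnt3 read 17390 to 23410, Myh1 17110 to 20350 and Acta1 11570 to 26560. Ucp1, a gene of brown fat, was at percentile 97.4 to 99.4. Tissue of the neck beside the airway in every sample stays open, since Tg and Pth were picked because they were bright. The muscle genes and Ucp1 were also picked after the values had been seen, and which tissue they come from was not tested. Whether the samples hold lung alone, or lung at all on the arrays with little Sftpc, stays open too, which limits what the alveolar and other lung lists can say. A probe set that takes up other transcripts was not tested.

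Of the 14 measured genes of the circadian clock list, which was fixed beforehand, 10 were higher on both arrays of title number 6 than on the other 3, 2 were lower on both (Arntl and Clock), and Nr1d1 and Cry2 did not separate the arrays. The 12 that separated them are more than in any of 10000 random sets matched on mean expression (mean 3.68, highest 11), and 27.1% of tested genes separate them. The random genes were drawn without regard to correlation, while the clock list had an estimated correlation of 0.27. Genes that move together separate arrays together, so the random sets make the count look rarer than it is. No other of the 25 lists had so large a share; the next with more than 5 genes was chemokines, with 8 of 14. Dbp read 1492 and 1500 on saline 6 and IL-13 6 against 360.4 to 639.3, Per2 573.3 and 542.2 against 129.4 to 189.4, and Arntl 279.1 and 218.8 against 807.2 to 855.1. The ratio of the 3' to the 5' control probe set of Gapdh also separated these arrays (0.656 and 0.741 against 0.835 to 0.988). So did that of Actb (1.2 and 1.14 against 1.22 to 1.5). Whether this bears on the clock genes was not tested. Title numbers that mark times of collection stay open as a hypothesis, since the test was chosen after these values had been seen and the labels give no unit.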
